A study of Obba rivulosa with 6 samples.

How the data were processed

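Messenger RNA of the wood-decaying white-rot basidiomycete Obba rivulosa, monokaryotic strain 3 A-2, was sequenced after 2, 4 and 8 weeks of growth on sticks of Norway spruce laid on water agar in the dark. There were 2 samples at each time, 6 in all. The labels do not say whether samples of one time came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical. The labels give no sequencing batch or date.

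The deposited files hold, for each sample, the length, the expected count and the FPKM value of each gene model. BWA, Bowtie and RSEM are named per the submitters' processing notes, and the columns are those of an RSEM gene table per the file headers. The versions, the settings, the genome build and the filters are not given in the sources used here. The expected counts were estimated by the authors and were not normalized. The authors' FPKM values are scaled by gene model length and library size, and are rounded in the files. A file lists only gene models with an expected count above 0, so a model missing from a file was taken as 0. In all, 12424 gene models were listed in at least 1 file and 11645 in every file, and no model of the other 779 exceeded an expected count of 54.7 in any library. The totals ran from 4908235 to 5154075 expected counts per library. Between 9.29% and 9.83% of the listed models had a count that was not whole, which arises when reads are divided between similar gene models. Such models are called shared-read models below, and 1469 models were so in at least 1 library. Counting error is small at this depth for abundant models, and a model with no read in a library could still hold up to 3 counts there.

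The files pair the identifiers (prefix jgi|Obbri1) with no product names, and no reference annotation was used. Gene models are therefore named by the JGI protein ID inside the identifier. Before the data were examined, 39 gene lists had been fixed by product name, among them the enzymes acting on plant cell walls and the genes of central carbon metabolism. None of these lists could be filled, so the counts and gene set tests planned for them are not analysed here.

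Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 (robust dispersion and fit) in R 4.3.3. TMM scaling and edgeR's filterByExpr with its minimum count of 10 were applied, which left 10889 gene models holding 99.89% to 99.92% of a library's reads. All 6 libraries entered one fit with a mean per week and no further term. Pairwise comparisons and an F test over the 3 weeks were adjusted by the Benjamini-Hochberg method, and a gene model was called changed at an adjusted p below 0.05. Standard errors and 95% intervals of log2 fold changes were derived from the F statistic and the unshrunken coefficients. The main rule for named models, fixed before the data were examined, needed product names and could not be used. Its fallback, fixed at the same time, was used instead. It takes for each comparison the 2 models that rose most and the 2 that fell most. They are taken among called models with at least 10 FPKM in the higher week and no overlap between the weeks. Levels are given as the authors' FPKM values, mean ± SD.

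The procedure was tested on simulated counts for the 10889 models with 200 of them changed by known folds. For week 4 against week 2 it recovered 66 of 100 models changed 2-fold and 99 of 100 changed 4-fold, with 7 false calls. For week 8 against week 4 it recovered 70 and 97 of 100, with 5 false calls. For week 8 against week 2 it recovered 76 and 95 of 100, with 5 false calls. Apart from the changed models, the simulated libraries shared one mean profile and one trend of spread with abundance. These figures therefore do not test the unequal spread between samples of the real weeks. Nor do they test the scaling where many models change.

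The spread of reads over gene models was described by the share of the most abundant models and by the effective number of models, which is the exponential of the Shannon entropy of the read shares. Samples of one week were compared by a chi-square test of their counts over models with at least 10 counts in the pair. Make-up measures were compared between weeks by exact two-sided permutation tests, whose smallest possible p with 2 samples per week is 0.333. To keep the noise of the week 4 libraries from entering both intervals, the reversals were also counted with a different week 4 library in each interval, in 1 fit with a mean for each of these libraries, whose variation was taken from the other weeks. To keep selection apart from measurement, the 100 most abundant models of a week were picked in replicate 1 and measured in replicate 2. The bounds of 10 and 1 FPKM used for detection classes, and the analyses of make-up, turnover and reversal, were chosen after the data had been examined. Alternatives tried were DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), other scalings and filters, the replicate number as a block, fits of only the samples compared, and each sample left out in turn. Make-up and permutation tests used Python 3.11.15 with scipy 1.17.1.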

Results

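The transcriptome of Obba rivulosa, a white-rot fungus that decays the lignin-rich wood of conifers, was followed through a long solid-state culture on spruce wood. The series asked how the needs of the fungus shift as the wood is broken down, by comparing weeks 2, 4 and 8 of growth. Each week was represented by 2 samples, with 4980809 and 5104386 expected counts at week 2, 4974674 and 4908235 at week 4, and 5078009 and 5154075 at week 8. Between 11233 and 11511 gene models reached 1 FPKM in a library.

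Samples of one week resembled each other more than those of any other week. Across the 10889 tested gene models, Pearson's r of log2 CPM was 0.990 between the samples of week 2, 0.974 between those of week 4 and 0.984 between those of week 8. The highest r between samples of different weeks was 0.924. These correlations run across genes, which are not independent replicates. The samples of a week differed by a median of 0.13 on the log2 scale at week 2, 0.28 at week 4 and 0.20 at week 8, and in each week by more than sampling noise (chi-square per degree of freedom 3.32, 25.6 and 12.6), so none were treated as the same library. The first principal component held 50.9% of the variance and set week 2 apart from weeks 4 and 8, and the second held 38.4% and set week 4 apart from week 8.

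**Figure D1:**
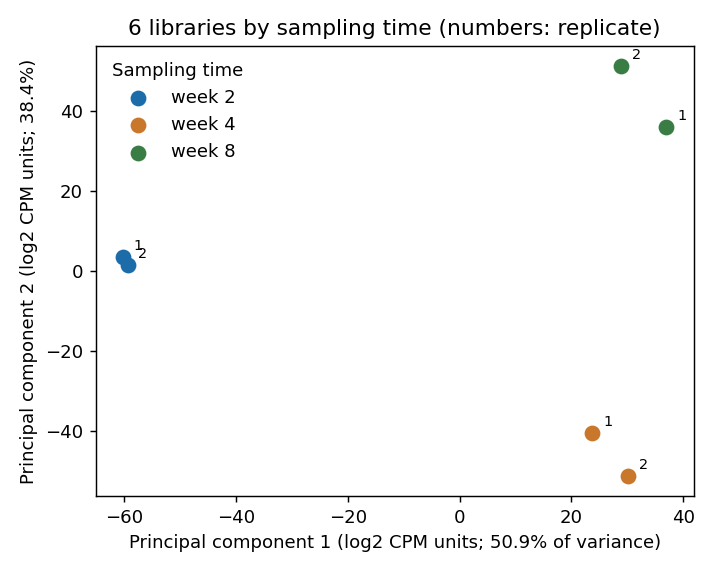
The 6 libraries are placed by the first (horizontal) and second (vertical) principal components of log2 CPM over 10889 gene models, coloured by sampling time and numbered by replicate. The components hold 50.9% and 38.4% of the variance, and the samples of each week lie together, with week 2 alone on the left.

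Most gene models active at one time were active throughout. At a bound of 10 FPKM, 7063 gene models reached it in all 6 libraries, which was 80.8% of the 8744 models that reached it in both libraries of at least 1 week. Few models met a strict pair of bounds for transcription in 1 week only. No gene model was at 10 FPKM or more in both libraries of week 2, or of week 4, while below 1 FPKM in the other 4 libraries, and 1 model was so for week 8. That model, jgi|Obbri1|282667|CE282490_8241, was chosen after its values were seen, and stood at 24.2 ± 13.1 FPKM at week 8 (SD, n = 2) against at most 0.84 FPKM in the other libraries. In the other direction, model 820226, described below, was the single model below 1 FPKM in both week 2 libraries and at 10 FPKM or more in all later ones. Levels nevertheless moved widely. The F test of edgeR called 5636 of 10889 gene models (51.8%) changed over time at an adjusted p below 0.05. For 3822 of all tested models (35.1%) the 95% intervals, not adjusted for multiple tests, of all 3 pairwise fold changes lay within 2-fold. These were counted whether or not they were called changed, so the 2 sets can overlap.

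Of the models changed over time, 1749 had their highest mean at week 2, 2102 at week 4 and 1785 at week 8. The lowest mean fell at week 2 for 1925 models, at week 4 for 1859 and at week 8 for 1852. This even spread depended on the scaling. With size factors (RLE), the highest mean fell at weeks 2, 4 and 8 for 1797, 2151 and 1626 of 5574 changed models. With upper quartile scaling it did so for 1716, 1915 and 2114 of 5745, so the leading week changed. With total counts only, the week of the highest mean was week 2 for 1154, week 4 for 1726 and week 8 for 3938 of 6818 changed models.

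From week 2 to week 4, 2123 gene models rose and 1927 fell, 37.2% of those tested. Of these, 1232 rose and 779 fell by at least 2-fold, and 367 rose and 238 fell by at least 4-fold. The median change over all tested models, whatever its direction, was 0.46 on the log2 scale, against median differences of 0.13 and 0.28 between the samples of weeks 2 and 4. The change compares means of 2 libraries and the differences compare single libraries, so noise enters them unequally. Among scarcely expressed models, the lowest quartile by mean FPKM (0.53 to 11.2 FPKM), 443 rose and 203 fell. In the highest quartile (57.3 FPKM and above) 679 rose and 743 fell. With total counts only these became 471 and 186 in the lowest quartile, and 698 and 685 in the highest.

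Among called models of at least 10 FPKM in the higher week, the one that rose most by week 4 was jgi|Obbri1|820226|estExt_fgenesh1_pm.C_1160017. It went from 0.545 ± 0.007 to 50.9 ± 11.8 FPKM (SD, n = 2), with 6 counts over both week 2 libraries and 552 over both week 4 libraries, a ratio of 91.9 with a 95% counting interval from 41.9 to 251. Its log2 fold change was 6.46 ± 0.37 (SE, adjusted p = 2.2e-06, edgeR). This SE is smaller than the counting error of 6 counts, so the counting interval is the better guide. Model jgi|Obbri1|790231|fgenesh1_kg.23_#_68_#_Locus9385v1rpkm2.65 went from 1.69 ± 0.03 to 83.0 ± 16.9 FPKM (SD, n = 2), a log2 fold change of 5.57 ± 0.29 (SE, adjusted p = 1.42e-06, edgeR), and stood at 5.64 ± 0.06 FPKM at week 8. With 16 counts over both week 2 libraries, the 95% counting interval of its ratio ran from 29.3 to 84.2. Among the models that fell, jgi|Obbri1|816782|estExt_fgenesh1_pm.C_70082 went from 504 ± 58.7 to 4.02 ± 0.34 FPKM (SD, n = 2), a log2 fold change of -6.99 ± 0.32 (SE, adjusted p = 1.18e-06, edgeR). Model jgi|Obbri1|788376|fgenesh1_kg.6_#_157_#_Locus6010v1rpkm12.86 had 17 and 24 counts at week 2 and none after rounding in the 4 later libraries. It was at least 6.84-fold lower at week 4 (adjusted p = 0.000975, edgeR) against a floor of 3 counts per library. It is a shared-read model, so its level is uncertain.

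The count of models changed between weeks 2 and 4 rested on both week 2 libraries, which were the most alike. It was 4050 with all libraries, 2053 without week 2 replicate 1 and 2218 without week 2 replicate 2.

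From week 4 to week 8, 1958 gene models rose and 2176 fell, 38.0% of those tested. By at least 2-fold, 680 rose and 1151 fell. Among abundant models, the highest quartile by mean FPKM, 888 were lower and 564 higher with TMM. In the second quartile (11.2 to 26.7 FPKM) 534 were higher and 409 lower. The lowest quartile also held more lower than higher models, 346 against 297. The median change over all tested models, whatever its direction, was 0.46 on the log2 scale, against median differences of 0.28 and 0.20 between the samples of weeks 4 and 8. Here too the change compares means of 2 libraries, and the differences compare single libraries.

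Model jgi|Obbri1|742218|e_gw1.382.21.1 fell from 128.1 ± 29.1 FPKM at week 2 to 4.72 ± 1.52 at week 4 and stood at 819 ± 287 FPKM at week 8 (SD, n = 2). Its log2 fold change from week 4 to week 8 was 7.13 ± 0.38 (SE, adjusted p = 5.18e-06, edgeR). Model jgi|Obbri1|803473|fgenesh1_pg.56_#_25 followed a like course, with 21.9 ± 1.54, 4.43 ± 1.53 and 416 ± 9.67 FPKM at weeks 2, 4 and 8 (SD, n = 2), and a log2 fold change of 6.24 ± 0.24 (SE, adjusted p = 1.48e-06, edgeR) over the second interval. By the same rule, the steepest fall in this interval was that of jgi|Obbri1|891790|estExt_Genemark1.C_3120005, from 174 ± 7.19 to 1.77 ± 0.91 FPKM (SD, n = 2), a log2 fold change of -6.90 ± 0.34 (SE, adjusted p = 2.21e-06, edgeR). Model jgi|Obbri1|278255|CE278078_466 stood at 361 ± 8.03 FPKM at week 2 and 310 ± 16.2 at week 4, then fell to 6.70 ± 1.57 at week 8 (SD, n = 2), a log2 fold change of -5.82 ± 0.23 (SE, adjusted p = 1.48e-06, edgeR).

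Week 8 levels depended on the scaling more than those of week 4. With total counts only, the median of all models rose by 0.31 on the log2 scale from week 4 to week 8 (0.01 with TMM), and 3642 models were called higher and 1351 lower. The highest quartile then held 942 higher and 602 lower, the second quartile 1028 higher and 233 lower, and the lowest quartile 572 higher and 201 lower. The count of changed models was 4134 with all libraries and 1743 without week 8 replicate 2.

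Many models changed by week 4 moved in the opposite direction by week 8. Whether the profile as a whole came nearer to week 2 depended on the measure. The root mean square of all log2 fold changes was 0.997 for week 4 against week 2, 0.893 for week 8 against week 4 and 1.014 for week 8 against week 2. The median change, whatever its direction, was 0.46, 0.46 and 0.36 in the same order. Of the 4050 gene models changed by week 4, 2034 (50.2%) changed in the opposite direction by week 8, made up of 1203 that rose and then fell and 831 that fell and then rose. Another 373 models moved the same way in both intervals, 125 of them up and 248 down. Independent lists of these lengths would give 771 models in opposite and 767 in the same direction. Such lists, here and below, are not a baseline for a return to week 2 levels, since both intervals share the week 4 level. Where week 4 differs from the other weeks, that level alone favours opposite calls. Both intervals use the week 4 libraries, and noise in these moves the calls of the intervals in opposite directions. With week 4 replicate 1 in the first interval and replicate 2 in the second, 1702 models changed in opposite directions and 429 in the same direction, against 760 and 757 for independent lists. With these libraries exchanged, 1688 and 449 did, against 768 and 764. Of the 2034 models, 1683 showed no called difference between weeks 8 and 2, which does not show that their levels were equal. With total counts only, no such difference was called for 1350 of 1919 models in opposite directions. It was 1179 of 1646 when only the 4 samples compared were fitted. The 2034 became 998 without week 2 replicate 1, 1066 without week 2 replicate 2 and 951 without week 8 replicate 2, which was 48.6%, 48.1% and 25.4% of the models then called changed by week 4.

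**Figure D2:**
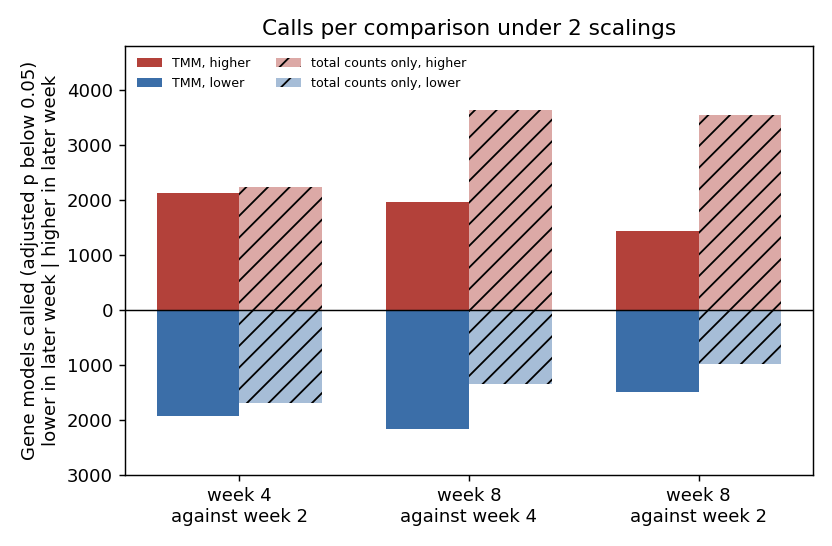
Bars give the number of gene models called higher (above 0) or lower (below 0) in the later week of each comparison, at an adjusted p below 0.05 in edgeR, with TMM scaling (solid) and with total counts only (hatched). TMM scaling centres the log ratios near 0, so the near-equal numbers of higher and lower calls under it are partly set by the scaling. With total counts only 3540 models were higher and 993 lower at week 8 against week 2.

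Between the ends of the series, week 8 against week 2, 1435 gene models were higher and 1496 lower at week 8, 26.9% of those tested. By at least 4-fold, 267 were higher and 328 lower. The highest quartile by mean FPKM held 350 higher and 643 lower models, and the lowest quartile 363 higher and 229 lower. With total counts only the median of all models rose by 0.37 on the log2 scale (0.05 with TMM), the split became 3540 higher and 993 lower, and the highest quartile held 872 higher and 464 lower and the lowest 751 higher and 156 lower. The prevailing direction among abundant models flipped with the scaling, which moved the median log2 fold change of the highest quartile from -0.06 to 0.26 and that of the lowest from 0.15 to 0.47. Under both scalings the highest quartile held fewer higher models for each lower one than the lowest quartile did. With size factors (RLE) and upper quartile scaling, 46.1% and 53.4% of the changed models were higher at week 8, against 49.0% with TMM.

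Model 820226, named above, kept rising and reached 189 ± 45 FPKM at week 8 (SD, n = 2). It held 2120 counts against 6 at week 2, a ratio of 278 with a 95% counting interval from 127 to 758. Its log2 fold change was 8.07 ± 0.35 (SE, adjusted p = 2.98e-07, edgeR), where the SE is again smaller than the counting error. Model jgi|Obbri1|791534|fgenesh1_kg.41_#_26_#_Locus8112v1rpkm4.83 rose through 12.3 ± 4.82, 52.1 ± 8.47 and 944 ± 181 FPKM at weeks 2, 4 and 8 (SD, n = 2), a log2 fold change of 5.94 ± 0.30 (SE, adjusted p = 4.92e-07, edgeR). Model 891790 ranked at number 32 of all models at week 2, with 1565 ± 171 FPKM (SD, n = 2), and was lower at week 8 by a log2 fold change of -10.10 ± 0.37 (SE, adjusted p = 1.85e-07, edgeR). Model jgi|Obbri1|851361|MIX10711_95_42 went from 1954 ± 311 through 82.5 ± 4.89 to 4.86 ± 1.15 FPKM (SD, n = 2), a log2 fold change of -8.97 ± 0.31 (SE, adjusted p = 1.85e-07, edgeR). It is a shared-read model, so its level is uncertain. The number of changed models was 2931 with all libraries, 1685 without week 2 replicate 1, 1754 without week 2 replicate 2 and 1944 without week 8 replicate 2.

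**Figure D3:**
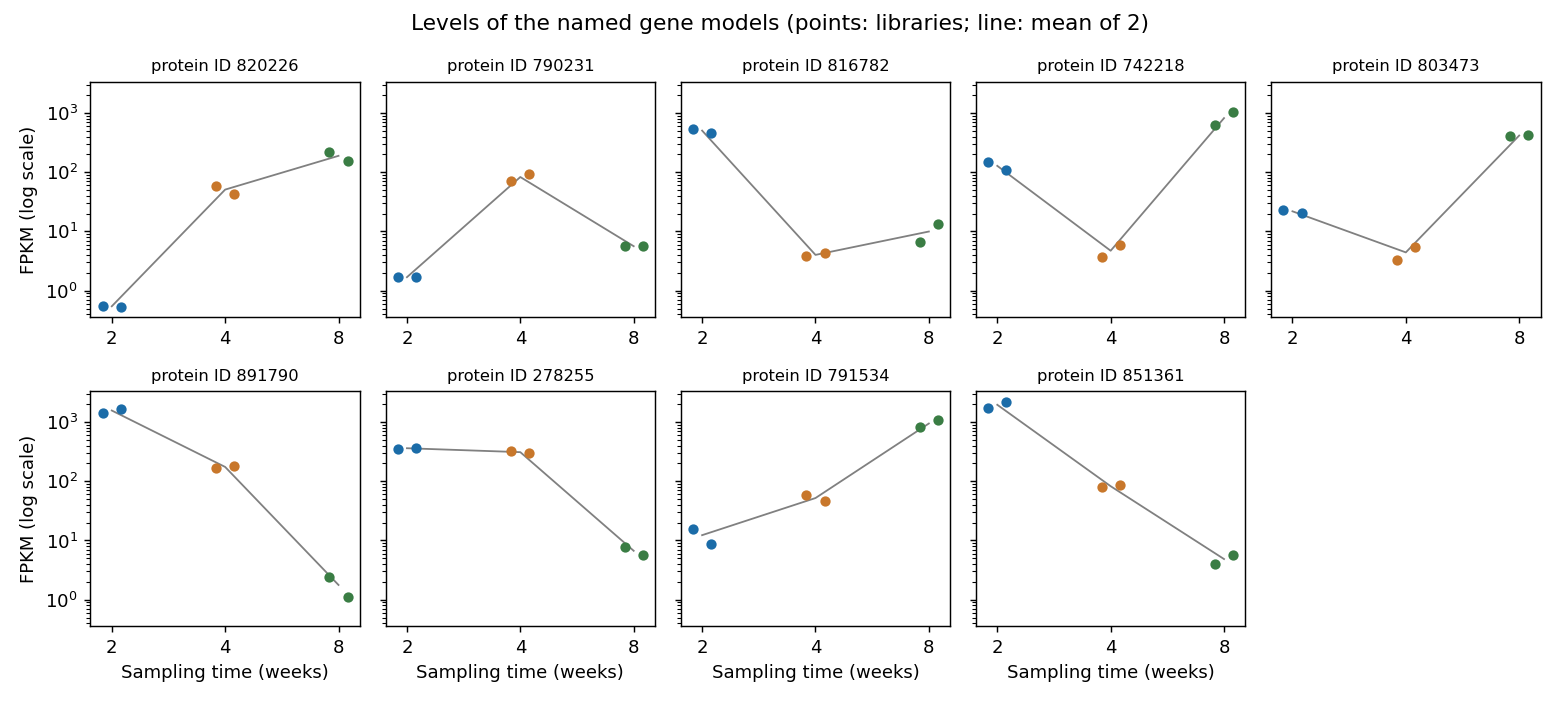
FPKM on a log axis against sampling time, shown as equally spaced weeks, for 9 of the named gene models, with a point per library and a line through the means of 2 libraries. Models 891790 and 851361 fell throughout, 820226 and 791534 rose throughout, and 742218 and 803473 were lowest at week 4 and highest at week 8.

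The reads were concentrated on fewer gene models early in the culture. The 100 most abundant models of a library held 23.6% ± 0.6 of its reads at week 2, 19.9% ± 0.1 at week 4 and 16.3% ± 0.02 at week 8 (SD, n = 2). The effective number of gene models was 3230 ± 70.5 at week 2, 3613 ± 93.5 at week 4 and 4517 ± 43 at week 8 (SD, n = 2). The difference of 383 between weeks 4 and 2 became 220 from FPKM shares and 190 without the 10 most abundant models of each library. The number of models at 1000 FPKM or more was 72 and 67 in the week 2 libraries and 50 and 53 in those of week 8. The weeks did not overlap in either the effective number or the share of the 100 models. An exact two-sided permutation test gave p = 0.333 for each pair of weeks, the smallest p that 2 samples against 2 allow.

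**Figure D4:**
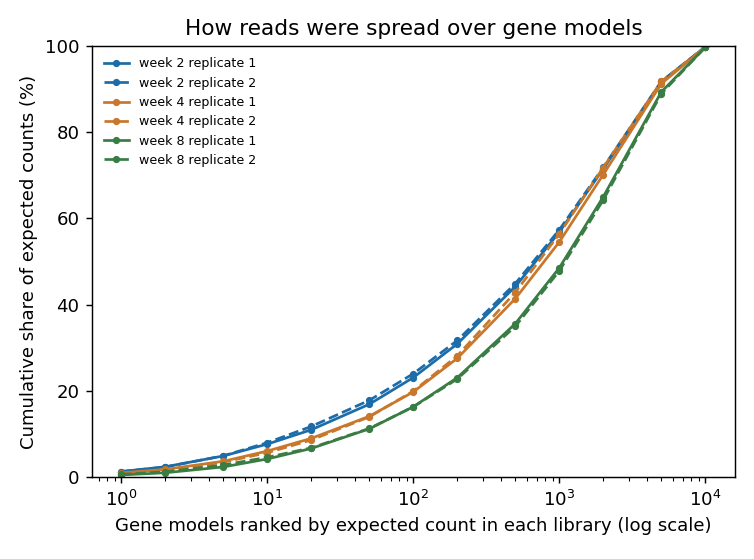
The cumulative share of expected counts (vertical, percent) is drawn against the rank of the gene models in each library (horizontal, log scale), with solid lines for replicate 1 and dashed lines for replicate 2. At 100 models the week 2 lines lie at 23.1% and 24.0% and the week 8 lines at 16.4% and 16.3%.

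The 100 most abundant models were shared less between weeks than between samples of a week. Of the 100 most abundant models of week 2 replicate 1, 96 were among the 100 most abundant of week 2 replicate 2, 44 among those of week 4 replicate 2 and 40 among those of week 8 replicate 2. The corresponding overlap between samples of one week was 74 for week 4 and 86 for week 8. Of the week 2 set, 72 models were among the 500 most abundant of week 4 replicate 2 and 64 among those of week 8 replicate 2. This set held 23.9% of the reads of week 2 replicate 2, 13.4% of those of week 4 replicate 2 and 8.13% of those of week 8 replicate 2. Its median level was 1075, 459 and 320 FPKM in these libraries, and 2 of its members were below 10 FPKM at week 8. The corresponding set of week 8 replicate 1 was already abundant early. It held 12.1% of the reads of week 2 replicate 2, 15.2% of those of week 4 replicate 2 and 15.8% of those of week 8 replicate 2, and 83 of its members were among the 500 most abundant models of week 2 replicate 2.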

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

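No fold change of a named model and no difference in effective number changed its sign, although the prevailing direction of the calls at week 8 depended on the scaling. The 12 fold changes of named gene models kept their direction and call in all 120 alternatives run on them. These models were picked as the largest called changes, so this says little about the other calls. DESeq2, upper quartile scaling and total counts only were among the alternatives not run on them. A bound of at least 2-fold left 2011 changed models for week 4 against week 2, 1831 for week 8 against week 4, 1748 for week 8 against week 2 and 747 that changed in opposite directions. Leaving out 1 library gave 2053 to 4339, 1743 to 4387 and 1685 to 3857 changed models for these comparisons and 951 to 2404 models in opposite directions, 25.4% to 55.4% of those changed by week 4, which was 37.1% at the 2-fold bound. Such fits leave a week with 1 library, which is assumed to vary like the others. Without a week 4 library both intervals rest on the other one and the spread of week 4 no longer enters, so those counts are not comparable with the full ones, and the cause was not tested further. With total counts only, an alternative chosen after the data were seen, as were leaving out shared-read models and those of the effective number, 4533 models changed between weeks 2 and 8. The limma fits on FPKM, which carry no TMM factors, gave 77.5% and 77.6% of these calls as higher at week 8 for pseudocounts of 1 and 0.1, and 73.1% and 73.3% for week 8 against week 4, compared with 49.0% and 47.4% in edgeR with TMM. The count for week 8 against week 2 was the lowest of the 3 comparisons with all libraries in one TMM fit. It was the highest when only the 4 samples compared were fitted (3775, against 3757 for week 4 against week 2 and 3241 for week 8 against week 4) and without week 4 replicate 2 (3857, against 3766 and 3846), and lay between the others with total counts only, in both limma fits and without week 8 replicate 2. The counts of changed models over time stayed within 1.5 times of 5636 in every alternative run.

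The replicate numbers do not mark a shared culture or day in the labels. Deviations of samples with the same number correlated at 0.01 for weeks 2 and 4, -0.07 for weeks 2 and 8 and -0.15 for weeks 4 and 8. With the replicate block, 3688, 3779 and 2717 models changed in the 3 comparisons and 5197 over time, and no count moved by over 1.5 times.

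The difference in effective number between weeks 8 and 2 was 1286, and 1102 from FPKM shares, 1068 without shared-read models and 1028 without the 10 most abundant models of each library. Between weeks 4 and 2 it was 383, and 220 from FPKM shares and 190 without the 10 most abundant models. The share of the top week 2 models also in the top of week 8 was 40% for 100 models and 22% for 50. The planned counts and set tests on gene lists were not run, since the files give no product names.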

Other observations

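The tests on neighbouring models, with a different week 4 library in each interval and of the most abundant models taking the counts were chosen after the results they bear on were seen, as were the alternatives with total counts only, without shared-read models and at 1000000 reads. Gene models with neighbouring numbers had correlated fold changes. The names of 3322 tested models give a prediction track, a scaffold and a running number, in the naming convention of the JGI, whose positions were not checked against an assembly here. The 500 pairs with consecutive numbers in one track and scaffold had Spearman's rho of 0.21 between their log2 fold changes for week 4 against week 2, 0.23 for week 8 against week 4 and 0.21 for week 8 against week 2. In the same order, models 2 numbers apart gave 0.08, 0.11 and 0.05, those 5 apart 0.03, 0.02 and 0.02, and those 10 apart 0.08, 0.06 and 0.05. These correlations run across genes, which are not independent replicates.

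For each comparison, rho of consecutive models exceeded the highest of 1000 shuffles of fold changes within track and scaffold (0.20, 0.21 and 0.19), each with a permutation p of 0.001, the smallest that 1000 shuffles can give, which adjustment over the 3 comparisons leaves at 0.001. The shuffles averaged 0.09, 0.11 and 0.08. Only paired models were shuffled, and a track and scaffold with a lone pair returns that pair in every shuffle. These averages may therefore hold part of the correlation of neighbours, and do not show a correlation across whole scaffolds. Reads divided between near-identical neighbours are argued against, since at least 83.4% of rho was left without shared-read models, although rho then exceeded the highest shuffle in 1 of the 3 comparisons. Overlap of neighbouring transcripts was not tested and stays open, and no biological explanation was tested.

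Of the gene models changed by week 4, 50.2% changed in the opposite direction by week 8, but 37.1% at a bound of 2-fold. The share was also lower without week 8 replicate 2. Sampling noise in the week 4 libraries that both intervals share is argued against as the whole source of the opposite calls. So is a single outlying week 4 library as the whole source. With a different week 4 library in each interval, models called in opposite directions outnumbered those called in the same direction by 3.97 and 3.76 times in the 2 arrangements, against 1.00 and 1.01 for independent lists, and 1523 and 1497 of the 2034 models were again called in the same opposite directions. A single outlying library then enters 1 interval alone, and 1702 and 1688 models were still called in opposite directions, against 760 and 768 for independent lists. These counts are not comparable with the 2034, since the spread of week 4 does not enter the fit. Both week 4 libraries still carry the week 4 level, which favours opposite calls wherever week 4 differs from the other weeks. The excess over independent lists therefore does not show a return to week 2 levels. Part of the 2034 may come from shared noise or an outlying library, and the split cannot tell how much. The count rested on other libraries too, with 998 models without week 2 replicate 1, 1066 without week 2 replicate 2 and 951 without week 8 replicate 2. The scaling is argued against too, with 1919 models in the lowest of 3 other scalings, 1599 of them among the 2034, and so are reads shared between gene models, with 1855 models without the shared-read ones, 1795 of them among the 2034. The sampling time stays open as a biological source, and a difference in handling or batch of the week 4 samples cannot be told apart from it, since the labels give no batch and each week has its own samples.

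The reads were spread over more gene models at week 8 than at week 2. Depth is argued against by the totals, which overlapped, with 4980809 and 5104386 counts at week 2 and 5078009 and 5154075 at week 8. Thinning could therefore hardly change the result. At 1000000 reads per library the lowest week 8 library exceeded the highest week 2 library by 1209 effective models. A few dominant models are argued against as the whole source, since 79.9% of the difference was left without the 10 most abundant models of each library, and shared-read models likewise, with 83.0% left without them. The sampling time stays open as a biological source and was not tested further, and a difference in handling or batch cannot be told apart from it, since the labels give no batch and each week has its own samples.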
